A study of Homo sapiens with 30 samples.

How the data were processed

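ATAC-seq peak lists of 30 libraries were analysed, in 15 groups of 2 libraries. Per the labels, nuclei were tagmented with Tn5 and the libraries sequenced on an Illumina HiSeq. Per the submitters' processing notes, the authors used Novoalign, SAMtools 1.3.1, Picard and MACS2 2.1.1.20160309 with GRCh38/hg38, but the notes do not give the order, the peak threshold or any shift of reads for the transposase, so none of these could be checked. In 26 of the deposited files each line is a peak called in that library alone. The fold of each deposited peak is the ratio of its summit pileup to the background, which the authors' caller took as 1 constant per library: all folds of a library were whole multiples of 1 step (tolerance 0.02). The deposited −log10 p and −log10 q belong to the summit, and a Poisson model with the same constant gave the deposited −log10 p again. The score that the authors deposited is 10 times the −log10 q without its decimals. A further column as deposited holds the distance of the summit from the peak start. For the 4 libraries titled 0.5 h and 1 h the authors deposited only summits of 1 bp with a −log10 q, without peak bounds, fold or background, on chromosomes 1 to 22, X and Y.

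Depth is not stated. The background constant, in fragments per base, was recovered from the steps of the fold and used as a relative depth. It also scales with fragment length. Peak lists hold no values below the threshold of the caller, so an absent peak is not a measured zero, and a shorter list moves every count in the same direction. No binomial interval can be given, and the precision of each mean rests on the number of libraries.

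Peaks on chromosomes 1 to 22 and X were used, and none was removed for lying in repeats or in sequence where reads map poorly. Peaks whose midpoint lay within 1 kb of a TSS in GENCODE release 44 were TSS-proximal and all others distal. For each cell line and comparison the peaks were merged where they overlapped by 1 bp or more and kept as regions when seen in at least 2 libraries. A gene locus was the gene body with 50 kb on each side, and protein-coding genes with a mean of at least 1 peak per library were tested. Loci of neighbouring genes can overlap and then share peaks, so counts of genes are not counts of separate sites. Log2 ratios of mean peak numbers have 0.5 added to both means. Consensus motifs (13) were searched on both strands in the 200 bp around each peak midpoint. Lists of genes (11) and motifs were fixed before the data were examined, as were the groups and the tests. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.

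The VCaP comparison set 4 vehicle libraries against 8 AU-15330 libraries of 4 to 24 h. Peak numbers, ratios, list shares and motif shares were compared by two-sided exact permutation tests over all 495 assignments of the libraries, regions by two-sided Fisher's exact tests, and gene loci by the permutation test on peak numbers. Adjustment was by Benjamini-Hochberg over all regions, genes, lists or motifs with a threshold of 0.05, and for lists of genes also over the list alone. List shares were set beside 10000 random sets of regions matched on class and on 5 bins of vehicle score. Odds ratios of lost regions were pooled over bins by the Mantel-Haenszel method with 95% intervals. The LNCaP drug comparison (2 against 4) and the genetic comparisons (2 against 2) cannot reach p under the threshold, so values and counts are given. Differences between effects were tested by permuting the line or time of the libraries, within vehicle and within AU-15330 libraries. A difference in level between lines or times therefore widens the spread of these tests. The processing folder recorded in the peak names was used as a possible batch. Replicate numbers did not pair the libraries: correlations of the deviations of replicates between groups lay between −0.0168 and 0.0444 in VCaP, 0.0411 and 0.103 in the LNCaP drug groups and −0.0108 and 0.00740 in the genetic groups, so the tests carry no replicate term. Replicate 1 had more peaks and a higher distal to TSS-proximal ratio in 5 of 6 VCaP groups and in 0 of 3 LNCaP drug groups.

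The genes named with values are, for each list, up to 4 members with the largest change of mean peak number, and always KLK3, KLK2, TMPRSS2, FKBP5, FOXA1, HOXB13, MYC, ERG, ETV1 in LNCaP, SMARCA2, SMARCA4, ACTB and GAPDH. The regions named are, per comparison and direction, up to 10 with the highest mean score among those present in all libraries of one side and absent from all of the other, 1 per nearest protein-coding TSS. Some genes and regions that the rule takes are not reported here. The genes with more peaks in VCaP (9) and the segments around them were named after their values were seen.

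The tests were tested on simulated data. With 500 of 49314 regions made to disappear in all drug libraries none was recovered, and with 2000 or 5000 all were, with 13 and 12 unchanged regions called. With a 4-fold loss of peaks, 2745 of 5000 changed genes (54.9%) were recovered and 18 unchanged genes called. With 2000 changed genes, or with a 2-fold loss, none was recovered. At this size regions were recovered all or none, and genes in part or not at all.

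Alternatives fixed at the same time were a score at or above the median of the line's peaks, equal numbers of the highest scoring peaks of every list, TSS windows of 500 bp and 5 kb, locus flanks of 10 kb and 100 kb, presence only where peaks cover at least 0.5 of a region, every merged region, no gene filter, whole peaks for motifs, the 8 h and 24 h libraries alone, another reference pair, a replicate block and leaving out each library. Chosen after seeing the data were a fold of at least 6 or 10, a run folder block, summits in place of midpoints, leaving out both libraries of a group, and leaving out peaks in segments above 100 (or, tried first, 150) peaks per Mb. Peaks on Y and on unplaced or alternative sequences were left out of all comparisons, so that each list is counted over the same chromosomes. The 4 libraries titled 0.5 h and 1 h were left out because their title names AU-15330 (spelled AU-CBH-15330) and their treatment label names vehicle. Their source name gives VCaP, and they have no cell line characteristic. Other data types of the study were not analysed here.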

Results

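Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 26 libraries of the human prostate cancer cell lines VCaP and LNCaP. VCaP carries a TMPRSS2-ERG fusion. The 12 VCaP libraries comprised 4 vehicle (DMSO) libraries, 2 at 8 h and 2 at 24 h, and 8 libraries treated with 1 µM AU-15330, 2 each at 4, 8, 12 and 24 h. AU-15330 degrades SMARCA2 and SMARCA4, the alternative ATPases of the SWI/SNF chromatin remodelling complexes. Loss of these or of other proteins was not measured in these libraries. The 14 LNCaP libraries comprised 2 vehicle libraries at 24 h, 4 libraries with 1 µM AU-15330, 2 at 12 h and 2 at 24 h, and 8 libraries of a genetic series with 2 libraries per group. These genetic groups carried a control guide RNA with a control hairpin, a SMARCA2 guide, a SMARCA4 guide, or a SMARCA2 guide with a doxycycline-induced SMARCA4 hairpin. A further 4 libraries have titles that name AU-CBH-15330, read here as AU-15330, at 0.5 h and 1 h and a treatment label that names vehicle. They entered no comparison. The peak lists state no read totals. The background level that each list implies, in fragments per base, scales with depth and fragment length and ran from 0.658 to 1.01 in the VCaP vehicle libraries and from 0.738 to 1.29 in the VCaP AU-15330 libraries. It differed by 1.05-fold on average between them (exact permutation p = 0.667). Whether replicate libraries came from separate cultures is not stated, so each p measures the spread between these libraries only.

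The first comparison asked how AU-15330 changes open chromatin at enhancers and promoters of VCaP cells. Under AU-15330, peaks away from transcription start sites (TSS) were lost far more often than peaks at them. Distal peaks, centred more than 1 kb from every annotated TSS, numbered 26535 ± 9567 per vehicle library (SD, n = 4) and 8312 ± 1754 per AU-15330 library (SD, n = 8). The mean was 3.05-fold lower on the log scale (two-sided exact permutation p = 0.00404, the smallest that 4 against 8 libraries allow), and all 8 AU-15330 libraries lay below all 4 vehicle libraries. TSS-proximal peaks numbered 16125 ± 1754 and 13286 ± 833, 1.21-fold lower (exact permutation p = 0.00808, n = 4 and 8). The distal share fell from 60.7% ± 7.95 to 38.2% ± 3.24, and the log2 ratio of distal to TSS-proximal peaks from 0.63 ± 0.47 to −0.70 ± 0.20 (difference −1.33, exact permutation p = 0.00404, n = 4 and 8). The total was 42661 ± 11315 peaks per vehicle library and 21597 ± 2573 per AU-15330 library, 1.93-fold lower (exact permutation p = 0.00808, n = 4 and 8).

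The lower distal share was present at the earliest drug time. It was 36.1% ± 1.04 at 4 h, 41.6% ± 3.99 at 8 h, 35.8% ± 1.97 at 12 h and 39.2% ± 2.75 at 24 h (SD, n = 2 each), against 55.8% ± 9.76 and 65.5% ± 1.47 in vehicle at 8 h and 24 h. Against vehicle of the same time, the log2 ratio differed by −0.84 at 8 h and by −1.56 at 24 h, where 2 libraries against 2 allow no exact permutation p under 0.333. A test of the difference between the 2 times gave an exact permutation p of 0.167. Its 36 assignments allow no p under 0.0556, so it could not have passed the threshold. The 2 processing folders recorded in the peak names each held 2 vehicle and 4 AU-15330 libraries. In 1 folder were vehicle 8 h with AU-15330 4 h and 8 h, in the other vehicle 24 h with 12 h and 24 h. Time and folder therefore cannot be told apart where 8 h is set against 24 h. Within the folders the log2 ratio differed by −1.004 and −1.66 (exact permutation p = 0.133 each, the smallest possible). The distal peak number differed by −1.14 and −2.08 within the folders, the total by −0.62 and −1.27, and the TSS-proximal number by −0.13 and −0.42, all on the log2 scale. The fall at TSS-proximal sites did not pass under other settings: the log2 difference was −0.22 above the median score (exact permutation p = 0.186), −0.17 at a fold of at least 10 (exact p = 0.230) and −0.22 in the 8 h and 24 h libraries alone (exact p = 0.0571, as for the total). When the 18474 highest scoring peaks of every list were taken it was 0.42 (exact p = 0.00404), which follows from the lower distal number, since the 2 classes then add up to the same total.

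**Figure D1:**
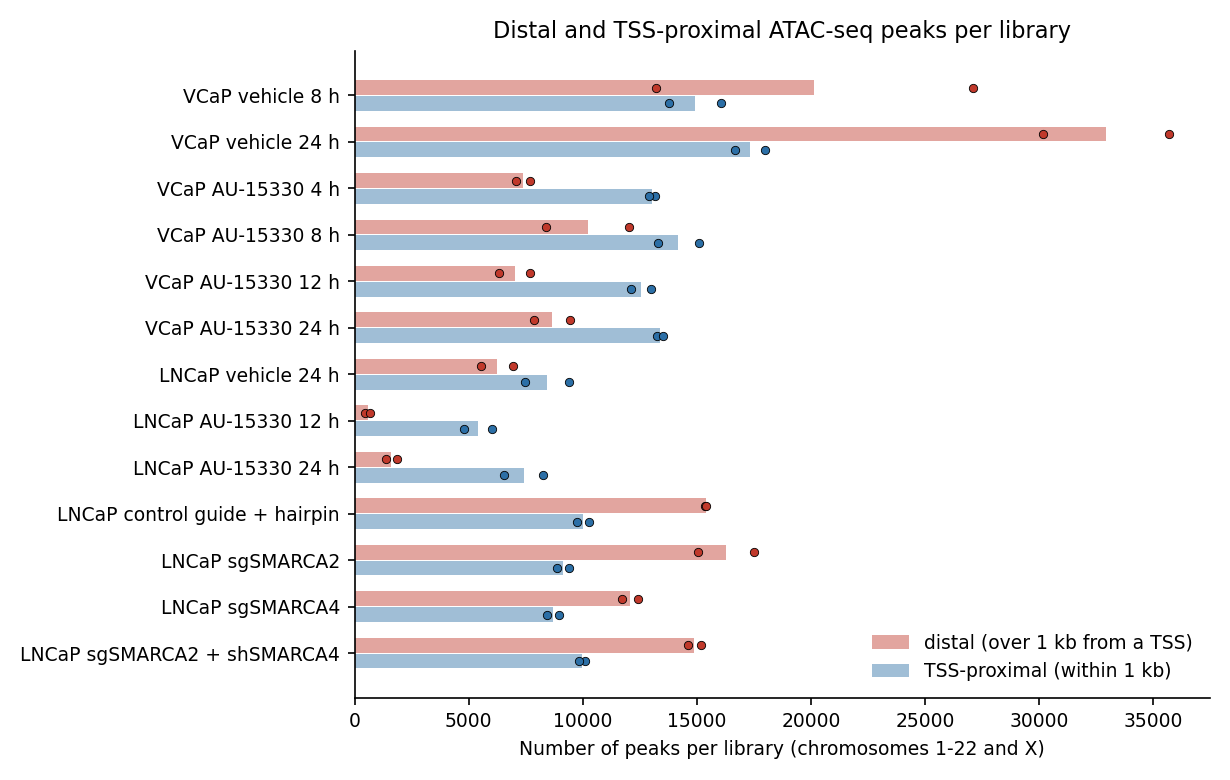
Number of distal (red) and TSS-proximal (blue) ATAC-seq peaks per library on chromosomes 1 to 22 and X, with bars for the mean of 2 libraries and points for each library. Distal peaks ran from 13214 to 35682 in VCaP vehicle libraries and from 6348 to 12024 in VCaP AU-15330 libraries.

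Region by region, 5581 of 49314 VCaP regions were lost, each with a peak in all 4 vehicle libraries and in none of the 8 AU-15330 libraries (Fisher's exact test, adjusted p = 0.0178). Of the lost regions, 5016 (89.9%) were distal. This was 15.6% of the 32253 distal regions tested, against 3.31% of the 17061 TSS-proximal regions. A peak in all 12 libraries was found at 9696 regions, of which 8219 were TSS-proximal. The strongest lost region lay on chromosome 8 at 64266328 to 64267508 (GRCh38), 313 kb upstream of BHLHE22, which encodes a neuronal transcription factor, and its mean −log10 q was 166 in the vehicle libraries. On the same chromosome, lost intergenic regions lay at 121431372 to 121432252 near HAS2, a hyaluronan synthase, at 108948480 to 108949265 near TRHR, the receptor of thyrotropin-releasing hormone, and at 116639674 to 116640672 near EIF3H, a translation initiation factor subunit. Introns held the lost regions of SNTG1 (chromosome 8, 50115216 to 50116160), LRRC69 (chromosome 8, 91107576 to 91108574), XKR4 (chromosome 8, 55343775 to 55344834) and ABCB4, a bile phospholipid transporter (chromosome 7, 87423882 to 87424572). The other strong losses lay near GALNT7 in an intron of GALNTL6 (chromosome 4, 172962272 to 172963219) and in intergenic sequence nearest to CNTNAP3C (chromosome 9, 62863178 to 62863757).

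In VCaP 7 regions had a peak in no vehicle library and in all 8 AU-15330 libraries, a number of gained regions that other splits of the 12 libraries also reached, and 75 regions had an unadjusted p under the threshold in this direction. The strongest gained region was intergenic, 2.70 kb downstream of the TSS of ID2, an inhibitor of basic helix-loop-helix factors (chromosome 2, 8684816 to 8686146), with a mean −log10 q of 12.5. Others lay in a coding exon of TMEM143 next to EMP3 (chromosome 19, 48333889 to 48334210) and upstream of PPARA, a fatty acid sensing nuclear receptor (chromosome 22, 46113888 to 46115298). The regions at NDRG1 (chromosome 8, 133238410 to 133242597), in an intron of ZBTB7B (chromosome 1, 155006684 to 155008900) and near IRS2 (chromosome 13, 109741816 to 109742351) lay in segments with unusually many peaks, described further on. Of the 49314 regions at least 1993 must reach the smallest possible p before any can pass. The count of lost regions was 12788 without vehicle 8 h replicate 2, the shortest vehicle list, and 6106, 5706 and 5829 without vehicle 8 h replicate 1, 24 h replicate 1 or 24 h replicate 2. It was 0 without both vehicle 8 h libraries and 0 with the 8 h and 24 h libraries alone. It was 1948 above the median score, 2556 with equal numbers of peaks, 1608 at a fold of at least 10 and 2253 where a peak had to cover at least 0.5 of the region, and the count of gained regions ran from 0 to 521 over the alternatives.

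The distal peaks that remained under AU-15330 had a different motif content. The forkhead motif bound by FOXA factors, which open chromatin for other factors, was found in 13.6% ± 0.774 of distal peaks in vehicle libraries (SD, n = 4) and in 3.83% ± 0.397 in AU-15330 libraries (SD, n = 8), 3.54-fold lower. The palindromic androgen response element fell from 0.279% ± 0.0281 to 0.0720% ± 0.0187, and the HOXB13 motif from 4.17% ± 0.131 to 1.63% ± 0.142. The ETS motif, bound by ERG, fell from 6.76% ± 0.0631 to 3.99% ± 0.269. The GATA motif fell from 3.03% ± 0.109 to 1.32% ± 0.114 and the grainyhead motif GRHL from 0.181% ± 0.0143 to 0.0574% ± 0.0108. With 6348 to 12024 distal peaks per AU-15330 library, the shares of the androgen response element and GRHL rest on few matches. Smaller falls were seen for AP-1 (4.03% to 3.29%), TEAD (4.17% to 3.42%) and RUNX (2.43% to 2.05%). The motif of the insulator protein CTCF rose from 3.55% ± 0.0505 to 7.67% ± 0.739 of distal peaks, 2.16-fold. Promoter-type motifs rose as well, SP/KLF from 1.12% ± 0.298 to 2.37% ± 0.274, NRF1 from 0.131% ± 0.0608 to 0.358% ± 0.0606 and NFY from 2.40% ± 0.169 to 3.005% ± 0.206. Each of the 13 motifs had a two-sided exact permutation p of 0.00404 (adjusted p = 0.00404), with no overlap between the 4 vehicle and 8 AU-15330 libraries. The RUNX motif had p = 0.117 by the same exact test when whole peaks were searched. These are shares of lists of different length, so a higher share is not a higher number of peaks.

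**Figure D2:**
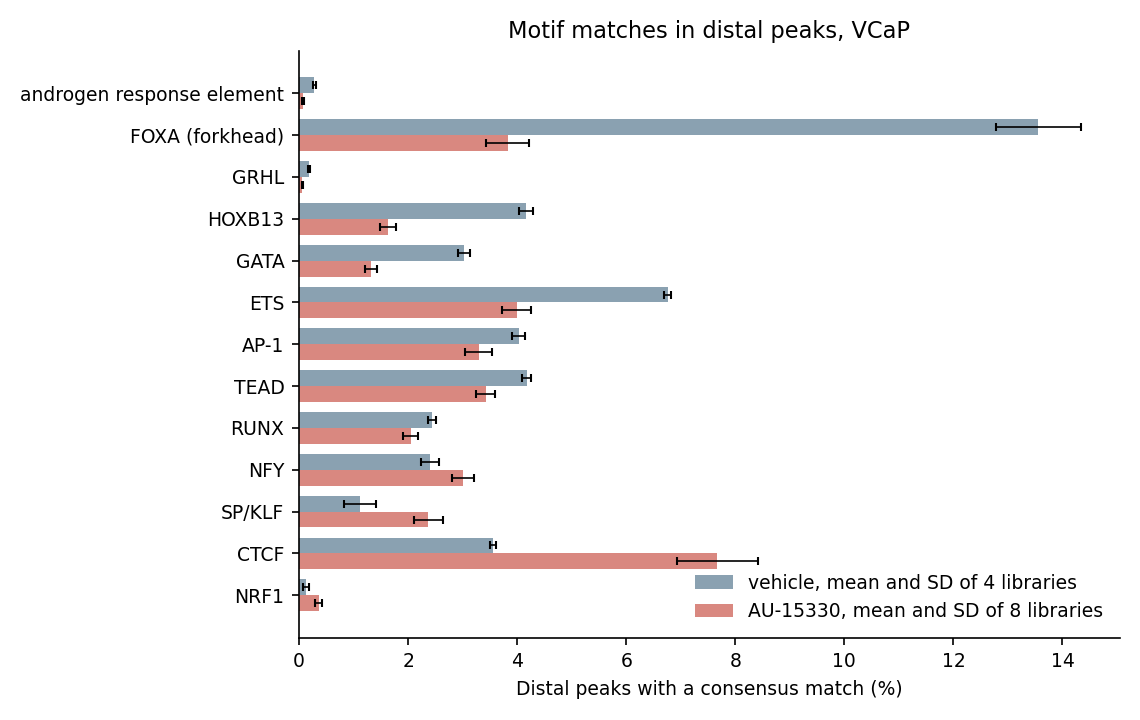
Share of distal VCaP peaks (percent) with a consensus match in the 200 bp around the peak midpoint, for 13 motifs, as mean and SD of 4 vehicle libraries and 8 AU-15330 libraries. The forkhead motif was at 13.6% and 3.83%, and the CTCF motif at 3.55% and 7.67%.

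The same contrast was seen between lost and kept regions. The forkhead motif was present in 18.7% of the 5016 lost distal regions and in 3.86% of the 1477 distal regions kept in all 12 libraries. Within bins of vehicle peak score its odds ratio was 6.20 (95% interval 4.69 to 8.19). Lost distal regions had a lower GC content (44.7% ± 7.57) than kept ones (55.0% ± 12.1; SD over regions), and within bins of both GC content and score the odds ratio was 3.37 (2.53 to 4.49). The HOXB13, ETS and GATA motifs had odds ratios of 2.13, 1.98 and 2.04 within the same bins. AP-1 had 1.14 (0.780 to 1.66), TEAD 1.205 (0.851 to 1.71) and RUNX 1.13 (0.721 to 1.78), intervals that include no difference. SP/KLF moved from 0.0658 within bins of score to 0.360 (0.189 to 0.686). CTCF had 0.0124 (0.00363 to 0.0423). Regions are not independent replicates, so these intervals cover sampling of regions only.

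Gene by gene, peaks were counted over the gene body and 50 kb on each side. Of 15557 protein-coding genes tested, 1879 (12.1%) had fewer peaks under AU-15330 and 9 had more, a number that other splits of the libraries also reached (exact permutation test of 4 against 8 libraries, adjusted p under the threshold), and 20 genes had an unadjusted p under it with more peaks. The median gene had a log2 ratio of −0.42 (0.75-fold), and with equal numbers of peaks from every list the median was 0.25 (1.19-fold), so the log2 ratios given for single genes with equal numbers are to be read against 0.25. At least 1258 genes must reach the smallest possible p before any can pass, and the count of genes with fewer peaks was 4481 without vehicle 8 h replicate 2, 0 without vehicle 8 h replicate 1, vehicle 24 h replicate 1 or vehicle 24 h replicate 2, and 0 without both libraries of any 1 drug time. With a replicate block or a run folder block, where no exact permutation p can fall under 0.00889, 0 genes had fewer and 0 more. It was also 0 above the median score or at a fold of at least 10 and 481 with equal numbers, where 862 genes had more.

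Among 27 androgen response genes with enough peaks, 6 had fewer peaks, 1 had more, and 20 did not pass; 8 had fewer with p adjusted over the list alone. STEAP4, a metalloreductase, had 8.75 ± 1.89 peaks in vehicle and 2.12 ± 0.835 under AU-15330 (adjusted p = 0.0333, exact permutation, n = 4 and 8). PMEPA1, an androgen-induced inhibitor of TGF-β signalling, had 21.8 ± 6.34 and 5.38 ± 3.11 (exact adjusted p = 0.0333). KLK2, which encodes a prostate kallikrein, had 6 ± 1.63 and 2 ± 0.926 (exact adjusted p = 0.0333), and ABCC4, HPGD and NCAPD3 also had fewer. KLK3, which encodes prostate-specific antigen, had 6 ± 1.83 and 2.5 ± 1.195 peaks and did not pass over all genes (exact adjusted p = 0.0616, and 0.0409 adjusted over the list alone). TMPRSS2 had 9.75 ± 6.02 and 3.75 ± 1.67 (exact adjusted p = 0.122), and FKBP5, a steroid receptor cochaperone, 4.25 ± 1.26 and 2.62 ± 1.41 (0.269). With equal numbers of peaks the log2 ratios were −1.34 for STEAP4 and −0.60 for PMEPA1, and 0.00 for KLK2, 0.14 for KLK3, −0.06 for TMPRSS2 and 0.52 for FKBP5. As a group, 69.6% ± 14.8 of the list's 208 regions had a peak in vehicle libraries and 42.6% ± 4.86 under AU-15330 (exact permutation, adjusted p = 0.0148). Random sets of regions matched on class and score fell by 33.5 percentage points on average and the list fell by 27.0, less than 99.8% of the 10000 sets, and with equal numbers the list's share was 0.962 points higher (exact adjusted p = 0.618).

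Among 11 prostate lineage and oncogenic transcription factor genes, 3 had fewer peaks and 8 did not pass, and 8 had fewer with p adjusted over the list alone. ERG, the fusion partner in VCaP, had 10.5 ± 5.80 peaks in vehicle and 0.875 ± 0.991 under AU-15330, GRHL2, an epithelial factor, had 10.2 ± 3.30 and 2.5 ± 0.926, and MYC had 10.5 ± 0.577 and 6.12 ± 1.13 (adjusted p = 0.0333 each, exact permutation, n = 4 and 8). With equal numbers their log2 ratios were −0.78, −0.70 and −0.09. FOXA1 had 10.5 ± 4.36 and 5.62 ± 1.302 peaks (exact adjusted p = 0.107) and HOXB13 5.75 ± 1.71 and 4.62 ± 1.92 (0.643), and both had positive log2 ratios, 0.46 and 0.30, with equal numbers. The share of the list's 130 regions with a peak was 76.3% ± 16.6 and 47.0% ± 4.64 (exact permutation, adjusted p = 0.0148), a smaller fall than in all 10000 matched sets, and 2.08 points higher under AU-15330 with equal numbers (exact adjusted p = 0.543).

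In the luminal epithelial list 4 of 10 genes had fewer peaks, among them the tight junction genes CLDN3 (10.2 ± 1.71 and 5.5 ± 0.756) and CLDN4 (10.5 ± 0.577 and 5 ± 1.07), and the count was 4 adjusted over the list alone. In the basal list KRT15, a keratin gene, was the 1 of 6 to pass (4.75 ± 0.957 and 1.5 ± 0.756; 2 adjusted over the list alone), while DST and LAMB3 did not (exact adjusted p = 0.107 and 0.131). In the neuroendocrine list 2 of 9 passed (3 adjusted over the list alone), among them the chromogranin gene CHGB (4.75 ± 1.71 and 2 ± 0.00), while POU3F2 and ENO2 did not (exact adjusted p = 0.0723 and 0.285). With equal numbers the log2 ratios of CLDN3, CLDN4 and CHGB stayed negative (−0.35, −0.54 and −0.38) and that of KRT15 was 0.70. KRT19, which passed in the luminal list, had the same log2 ratios as KRT15 (−1.39, and 0.70 with equal numbers). Loci of neighbouring genes share peaks, so the calls of KRT15 and KRT19 are not separate results. None of the 9 mesenchymal genes passed by the permutation test, over all genes or adjusted over the list alone; 4 of them, CDH2, ZEB2 and COL1A2 included, had fewer peaks at an unadjusted p under the threshold (adjusted p = 0.107 for these 3). The share of regions with a peak fell in these 4 lists, luminal from 79.7% ± 14.4 to 51.7% ± 3.39 (adjusted p = 0.0148), basal from 73.7% ± 22.2 to 36.5% ± 8.31 (0.0148), neuroendocrine from 80.1% ± 14.5 to 56.8% ± 4.71 (0.0317) and mesenchymal from 75.6% ± 27.8 to 38.4% ± 4.65 (0.0395; exact permutation, n = 4 and 8). Each fall lay inside the spread of its matched sets (percentiles 80.4, 17.6, 70.5 and 49.5), and with equal numbers the luminal, basal and neuroendocrine shares were 4.08, 4.89 and 5.30 points higher under AU-15330, none past the threshold. The mesenchymal call was kept on leaving out vehicle 8 h replicate 2, AU-15330 4 h replicate 1 or 24 h replicate 1 and lost without each of the other 9 libraries (exact adjusted p up to 0.119), and the neuroendocrine call was lost without vehicle 8 h replicate 1 or either vehicle 24 h replicate (0.0952 each).

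Among the SWI/SNF subunit genes, ARID1B was the 1 of 15 to pass (19.2 ± 5.68 and 6.38 ± 1.41 peaks, adjusted p = 0.0333 by exact permutation, n = 4 and 8; 0 adjusted over the list alone, where 0.0606 was its adjusted p), and its log2 ratio with equal numbers was −0.84. SMARCA2 had 4.25 ± 1.26 and 2.25 ± 0.463 peaks and BRD9 4.5 ± 1.29 and 1.75 ± 0.886 (exact adjusted p = 0.0616 each), and both had positive ratios with equal numbers, 0.51 and 0.36. SMARCA4 had 0.5 ± 0.577 and 0.625 ± 0.744 and too few peaks to be tested. Peaks at these loci do not measure the SMARCA2 and SMARCA4 proteins. None of 13 housekeeping genes passed by the permutation test, over all genes or adjusted over the list alone, and 4 had fewer peaks at an unadjusted p under the threshold. ACTB had 6.5 ± 1.29 and 6 ± 1.51 peaks (exact adjusted p = 0.915), GAPDH 4 ± 1.41 and 4.25 ± 0.463 (0.973), and PGK1 had 11.2 ± 3.50 and 5.88 ± 0.835 with the smallest adjusted p of these 3, 0.0903 (0.0242 unadjusted). In the cell cycle list 1 of 11 passed, the mitotic kinase gene CDK1 (4.75 ± 0.5 and 2 ± 0.00; 1 adjusted over the list alone), and in the blood cell list 1 of 4, SPI1, a myeloid factor gene (4 ± 0.00 and 2.75 ± 0.463; 1 adjusted over the list alone), and both had positive log2 ratios with equal numbers, 0.15 and 0.38. The share of regions with a peak fell for SWI/SNF (78.2% ± 10.1 to 56.9% ± 3.44, adjusted p = 0.0148), housekeeping (84.5% ± 7.45 to 68.3% ± 3.31, 0.0148) and cell cycle genes (82.0% ± 13.8 to 63.2% ± 4.19, 0.0389) by exact permutation tests, and not for blood cell genes (83.7% ± 20.9 and 62.5% ± 11.6, 0.0667). Matched sets fell more than the SWI/SNF, housekeeping, cell cycle and blood cell lists in 91.6%, 98.65%, 96.5% and 75.2% of cases. With equal numbers all 4 shares were higher under AU-15330, by 14.4, 12.8, 25.3 and 25.6 points (SWI/SNF, housekeeping, cell cycle and blood cell genes; exact adjusted p = 0.0148, 0.0533, 0.0148 and 0.0333), so the direction depended on how many peaks of each list were counted. The cell cycle call was lost without vehicle 8 h replicate 1, either vehicle 24 h replicate, AU-15330 4 h replicate 1 or 12 h replicate 2 (exact adjusted p up to 0.119), and the blood cell list passed without vehicle 8 h replicate 2.

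Set against the median of all genes, the median log2 ratio of the androgen response genes lay at −0.19, and at −0.25 with equal numbers of peaks, with 21 and 17 of 27 genes below the median gene. For the lineage factors the values were −0.47 and −0.23 (8 and 6 of 11 genes below) and for the mesenchymal genes −0.26 and −0.58 (6 of 9 below in both). The basal genes were at −0.58 and 0.07, the neuroendocrine genes at −0.11 and −0.03, and the luminal genes at 0.04 and 0.35. The SWI/SNF genes were at 0.15 and 0.13, as were the cell cycle genes, the housekeeping genes at 0.31 and 0.03, and the blood cell genes at 0.19 and 0.31. These medians were not tested.

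A peak was present at 59.2% ± 7.26 of the 79 regions of the immediate early and AP-1 genes in vehicle libraries and at 60.0% ± 8.12 under AU-15330 (exact permutation p = 0.917, n = 4 and 8), where matched sets fell by 16.9 points and all 10000 fell more. Relative to the median gene their median log2 ratio was 0.37, and 0.56 with equal numbers. None of the 11 genes passed the permutation test, over all genes, adjusted over the list alone or unadjusted. FOSB had 5.75 ± 1.26 and 7.75 ± 2.82 peaks (exact adjusted p = 0.453), JUND had 3.25 ± 1.5 and 4.75 ± 1.04 (0.254) and ATF3 had 4.5 ± 1.29 and 3.12 ± 0.354 (0.169). The list's share was 24.8 points higher under AU-15330 with equal numbers (exact adjusted p = 0.0148) and 11.7 points lower at a fold of at least 10 (−11.7, exact adjusted p = 0.0333), so its direction depended on which peaks were counted.

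All 9 genes with more peaks lay in segments of very high peak density in VCaP, at 145 to 560 peaks per Mb against a median of 15.7 over the tested genes. On chromosome 13 between 108911998 and 112089090 these were IRS2, COL4A1, COL4A2, CARS2, ARHGEF7, TEX29 and SOX1, and on chromosome 8 between 133024077 and 133507966 CCN4 and NDRG1. Loci of neighbours such as COL4A1 and COL4A2, or CCN4 and NDRG1, overlap and share peaks, so these genes are not separate counts. IRS2, an insulin receptor adaptor gene, had 36.5 ± 3.11 peaks in vehicle and 68.6 ± 19.6 under AU-15330, and NDRG1, a stress and androgen response gene, had 36.8 ± 10.8 and 60.9 ± 5.82 (adjusted p = 0.0333 each, exact permutation, n = 4 and 8). At a fold of at least 10 NDRG1 had 2.25 fewer peaks on average under AU-15330 (−2.25). Without the peaks of such segments 3 regions were gained, and 0 genes had more, as all 9 lie in them. The LNCaP control libraries held a mean of 25 peaks in the chromosome 13 segment, where VCaP vehicle libraries held 944 (944.5).

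The LNCaP comparison asked whether the same compound acted alike in a second line. LNCaP cells lost most distal peaks under AU-15330. Distal peaks numbered 6250 ± 996 in vehicle (SD, n = 2) and 1094 ± 640 under AU-15330 (SD, n = 4), 6.57-fold lower, and the distal share was 42.6% ± 0.00184 and 13.7% ± 4.92. The log2 ratio of distal to TSS-proximal peaks differed by −2.30, −2.83 at 12 h and −1.77 at 24 h. The total was 14679 ± 2338 and 7496 ± 2070 peaks, 2.00-fold lower, and the difference was larger than the spread between replicates. The exact permutation p was 0.133 for distal peaks, the total and the ratio, the smallest that 2 against 4 libraries allow, and 0.267 for TSS-proximal peaks. The forkhead motif was found in 20.7% ± 1.21 of distal peaks in vehicle and in 3.35% ± 0.714 under AU-15330, and the CTCF motif in 2.05% ± 0.329 and 9.90% ± 2.13. The androgen response element was at 0.256% ± 0.0973 and 0.295% ± 0.123. With 447 to 1846 distal peaks per AU-15330 library that share rests on very few matches, so no direction is drawn from it. All LNCaP AU-15330 libraries came from a processing folder that holds no vehicle library, so folder and drug cannot be told apart in LNCaP. Background levels differed by 1.12-fold between the groups (exact permutation p = 0.533).

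In LNCaP 3390 of 9620 regions with a peak in both vehicle libraries had none in all 4 AU-15330 libraries, 81.6% of the distal and 9.33% of the TSS-proximal regions, and 29 regions had the opposite pattern. The strongest lost regions lay upstream of SGCD, a muscle sarcoglycan gene (chromosome 5, 155546066 to 155546425, intergenic), upstream of IGSF9B (chromosome 11, 134008506 to 134009147, intergenic), and in introns of RBMS3 (chromosome 3, 28788496 to 28789004) and TRMT11 (chromosome 6, 126054217 to 126054725). The others were nearest to TENM3, PTPRC, OSTF1, ASXL3, PLXNA2 and PTBP2. The strongest gained region was intergenic, nearest to WSB1 at a distance of 699 kb (chromosome 17, 26594781 to 26595114), and several gained regions lay at the TSS of a gene, such as INHBA, the activin A subunit gene (chromosome 7, 41705159 to 41705551, UTR). How well reads map at the region nearest to WSB1 was not checked, so an artefact of mapping stays open there. ETV1, the ETS factor gene rearranged in LNCaP, had 2.5 ± 0.707 peaks in vehicle and 0.75 ± 0.5 under AU-15330, STEAP4 had 3 ± 0.00 and 0.25 ± 0.5, ARID1B 7.5 ± 2.12 and 2.5 ± 1.29, and NDRG1, higher in VCaP, 5.5 ± 0.707 and 1.5 ± 0.577 (SD, n = 2 and 4, not tested). The count of lost regions was 8007 and 5929 without vehicle replicate 1 or 2, since fewer libraries must then agree, and 1117 above the median score, 891 with equal numbers and 805 at a fold of at least 10.

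The genetic series asked what losing SMARCA2, SMARCA4 or both did in LNCaP. Control guide and hairpin libraries had 25393 ± 359 peaks (SD, n = 2), of which 60.6% ± 0.826 were distal. The SMARCA4 guide libraries had 20765 ± 863 peaks and 12070 ± 488 distal peaks, against 15378 ± 7.78 distal peaks in control, and the log2 peak number lay between −0.47 and −0.26 above the median score and at a fold of at least 6 or 10. The SMARCA2 guide and the combined group had 25409 ± 2111 and 24860 ± 605 peaks. The distal share was 64.0% ± 1.47 with the SMARCA2 guide, 58.1% ± 0.0653 with the SMARCA4 guide and 59.9% ± 0.231 with the SMARCA2 guide and SMARCA4 hairpin. The log2 peak number differed from control by −0.00, −0.29 and −0.03, and the log2 ratio of distal to TSS-proximal peaks by 0.21, −0.15 and −0.04. With 2 libraries against 2 no exact permutation p can fall under 0.333. Per the labels, the control and the combined group received doxycycline at 1 µg/ml for 72 h and the single-guide groups none, so the doxycycline and the perturbation cannot be told apart in the single-guide groups. The signs of 4 of these 6 differences turned under other settings: the SMARCA4 guide's ratio to 0.24 with equal numbers of peaks and, at a fold of at least 10, the SMARCA2 guide's number to 0.13 and the combined group's number and ratio to 0.19 and 0.14.

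Regions lost from both libraries of a perturbation made up 12.7% of the distal and 8.10% of the TSS-proximal control regions with the SMARCA2 guide (1959 of 18233), 21.4% and 10.2% with the SMARCA4 guide (3034 of 18246), and 18.2% and 5.99% in the combined group (2364 of 18204). The opposite pattern was found at 2045, 962 and 2193 regions. The 3 comparisons share the same 2 control libraries, and an intergenic region nearest to WSB1 (chromosome 17, 26885722 to 26885884) was among the strongest lost in all 3. Mapping of reads at that region was not checked either. The strongest regions lost with the SMARCA2 guide, and with the SMARCA4 guide as well, included an intron of NEDD4L, a ubiquitin ligase gene (chromosome 18, 58313472 to 58314029). With the SMARCA4 guide they included a site just upstream of MAML2, a Notch coactivator gene (chromosome 11, 96343168 to 96343614), and the UTR of CDK1 (chromosome 10, 60778207 to 60778885). In the combined group they included an intron of UAP1 (chromosome 1, 162568597 to 162569254). The forkhead motif was in 19.1% ± 0.151 of control distal peaks, 20.2% ± 0.213 with the SMARCA2 guide, 19.3% ± 0.0523 with the SMARCA4 guide and 18.3% ± 0.507 in the combined group. The androgen response element was in 0.371% ± 0.0462 of control distal peaks and in 0.212% ± 0.00800, 0.182% ± 0.00737 and 0.168% ± 0.0142 in the 3 perturbed groups (SD, n = 2 each). These shares rest on few matches and on the same control libraries, and their differences were not tested. The CTCF motif was at 1.84% ± 0.134 in control and 3.004% ± 0.161 in the combined group. ARID1B had 17.5 ± 2.12 peaks in control and 13.5 ± 3.54 in the combined group, and STEAP4 5 ± 1.41 and 5 ± 0.00. Counts of lost regions depended on the 2 libraries per group: the highest without a control replicate were 6055, 7701 and 6344, and with equal numbers of peaks they were 574, 516 and 611.

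**Figure D3:**
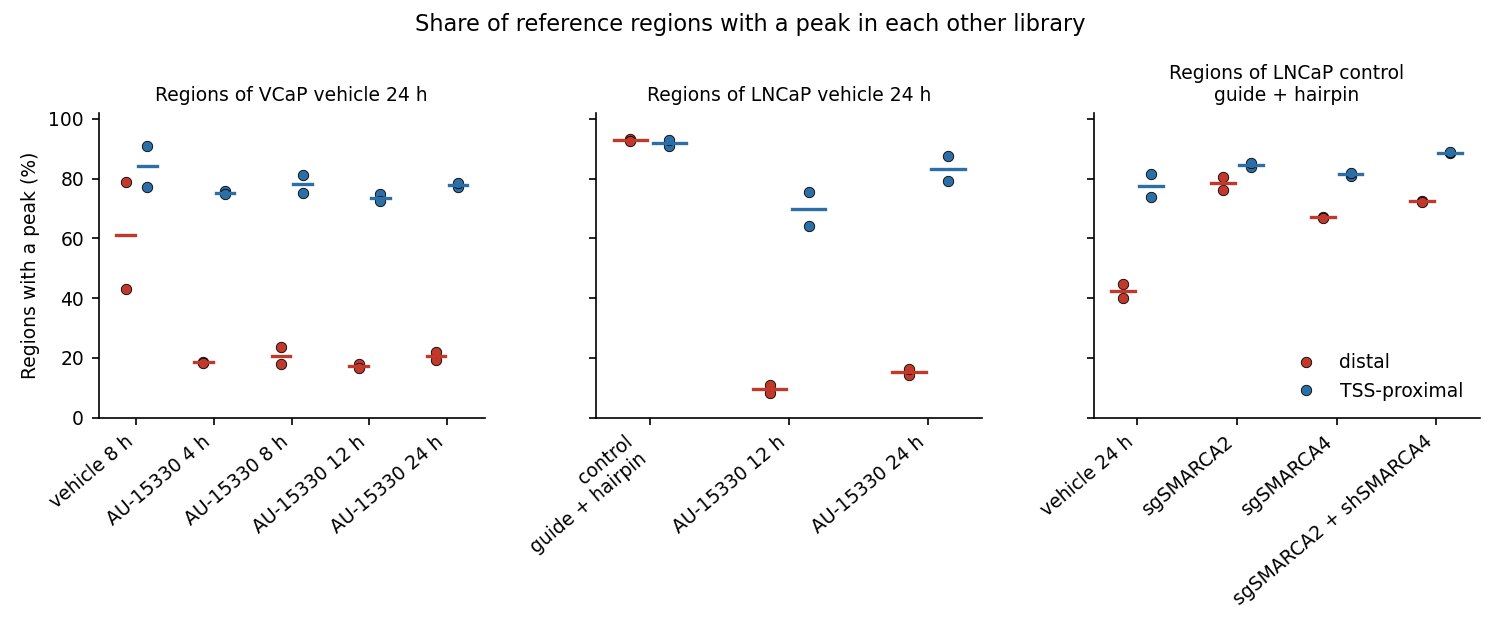
Share (percent) of regions with a peak in both libraries of a reference pair that have a peak in each other library, for distal (red) and TSS-proximal (blue) regions, with points for libraries and lines for means of 2. Distal regions of VCaP vehicle 24 h were retained at 19.3% on average in the 8 AU-15330 libraries and at 61.0% in vehicle 8 h.

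Measured against regions of the matching control libraries, AU-15330 left fewer distal regions open than the genetic perturbations did, a difference that was not tested. The LNCaP drug and genetic series differed in background level. It ran from 0.496 to 0.786 in the vehicle and AU-15330 libraries and from 1.05 to 1.29 in the genetic series. How far the compound, the guides and the hairpin lowered the proteins was not measured here. Whether the compound also lowered other proteins was not measured either, so drug and genetic values are not like for like. Of the distal regions with a peak in both VCaP vehicle 24 h libraries, 61.0% ± 25.3 (SD, n = 2) had a peak in vehicle 8 h libraries, the background of this measure, and 19.3% ± 2.32 (SD, n = 8) in AU-15330 libraries. Of the fifth with the highest scores, 95.4% and 33.7% ± 2.22 did. TSS-proximal regions were retained at 84.1% ± 9.62 and 76.3% ± 2.71. In LNCaP, distal vehicle regions were retained at 92.8% ± 0.511 in the control guide libraries, the background, and at 12.4% ± 3.50 (SD, n = 4) under AU-15330. Distal regions of the control guide libraries were retained at 78.5% ± 3.11 with the SMARCA2 guide, 67.0% ± 0.0340 with the SMARCA4 guide and 72.5% ± 0.278 in the combined group (SD, n = 2), and at 42.5% in the LNCaP vehicle libraries, the background there. Both LNCaP backgrounds, 92.8% and 42.5%, set series of unlike background level against each other. Neither therefore gives the retention between untreated libraries of like depth. Of the fifth with the highest scores, 99.6%, 98.05% and 98.5% were retained in the 3 perturbed groups, against 29.5% ± 2.75 of the corresponding vehicle regions under AU-15330. The VCaP drug value was 30.8% with vehicle 8 h as the reference and 12.0% where peaks had to cover at least 0.5 of a region.

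Among regions with a peak in the vehicle libraries of both lines, those lost in VCaP were largely lost in LNCaP as well. Such regions cover only a part of the VCaP losses, since 19572 regions were lost in VCaP at 24 h against vehicle 24 h. Of 8358 regions with a peak in both lines' vehicle 24 h pairs, 2041 were lost in both VCaP AU-15330 24 h libraries and 2524 in both LNCaP ones, and 1948 were lost in both lines, 95.4% of the VCaP losses, where losses independent within distal and TSS-proximal regions would give 1466. The odds ratio within class and score was 49.2, from 32.3 where peaks had to cover at least 0.5 of a region to 158 with equal numbers. It was 40.5 among distal and 150 (149.9) among TSS-proximal regions. The effect of the drug on the log2 ratio of distal to TSS-proximal peaks differed by 0.97 between the lines (exact permutation p = 0.261). That test exchanged libraries between the lines, whose vehicle libraries already differed in this ratio. It therefore cannot set the difference against the spread of replicate libraries. Between LNCaP AU-15330 at 24 h and the combined genetic group the overlap was small in number: of 8469 shared regions the drug removed 2994 and the combined perturbation 182, with 144 removed by both against 105 for losses independent within distal and TSS-proximal regions (odds ratio within class and score 4.34). The SMARCA4 guide removed 311, of which 164 were also removed by the drug (odds ratio 1.596), and the SMARCA2 guide 204, of which 101 were (odds ratio 2.41).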

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

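Of the tests in this part, the comparison with LNCaP libraries in dense segments was chosen only after the result was seen. The 3 results described first stood out, 1 because a library lay far from the others of its group, 1 because 2 groups lay on opposite sides of their control, and 1 in libraries that no comparison used.

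AU-15330 8 h replicate 1 had 15072 TSS-proximal peaks, the highest of the 8 VCaP AU-15330 libraries, and its gap to the next library was 0.527 of the range against a critical value of 0.526; chance marks about 1 in 20 groups, and 18 combinations of group and measure were examined.

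The log2 ratio of distal to TSS-proximal peaks was 0.36 higher with the SMARCA2 guide than with the SMARCA4 guide, with both libraries of each group on opposite sides of the control mean; the difference was not tested, and the sign for the SMARCA4 guide turned to 0.24 with equal numbers of peaks and to 0.08 at a fold of at least 10.

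In the 4 VCaP libraries titled AU-15330 0.5 h and 1 h, whose treatment label names vehicle, 1.63% of peaks on average lay on chromosome Y (1.44% to 1.87%), against 0.133% to 0.240% in the other VCaP libraries, and 3.01% lay on X against 3.70% to 5.81%.

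Among the 18474 strongest peaks of each list, these 4 libraries lay between the vehicle and AU-15330 libraries in forkhead motif content, though not in all motifs: over all summits TEAD was at 4.11% in vehicle, 5.14% at 0.5 h and 5.32% at 1 h, and CTCF at 4.06%, 3.56% and 3.23%, against 3.42% and 7.67% around peak midpoints under AU-15330. The share of distal peaks with the motif was 11.4% and 10.8% in the 0.5 h libraries and 5.39% and 5.83% in the 1 h libraries, against at least 13.8% in vehicle and at most 4.30% under AU-15330, which argues against weak extra peaks diluting the lists. The highest of 5 score bins of distal vehicle regions held a summit at most at 76.0% (75.95) in a 1 h library, below the 90.8% of the lower vehicle 8 h library and the 96.9% of the lower 0.5 h library, which argues against other peak calling settings as the whole explanation. The segments with dense peaks in VCaP held at least 3.94% of the summits in each of the 4 libraries and at most 0.613% in the LNCaP libraries, which argues against LNCaP cells, and other lines were not compared. All 4 share a processing folder with no other library, so a batch cannot be told apart from the treatment, and treatment with the compound, which the 2 labels answer differently, stays open as an untested explanation.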

How the results depend on the processing

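Chosen only after the results were seen were the settings with a fold of at least 6 or 10, the run folder block, peak summits, segments of dense peaks left out, and both libraries of a group left out. In VCaP the fall of distal peak number (log2 −2.46 to −0.56) and of the distal to TSS-proximal ratio (−2.30 to −0.98) kept direction and side of the threshold in all 12 alternatives run beside those leaving out 1 library, and in all of those. Motif shares did so in 311 of 312 cases, with RUNX in whole peaks the exception (exact permutation p = 0.117). In LNCaP the ratio under AU-15330 lay between −2.30 and −1.95 in 8 alternatives, and between −2.49 and −2.07 on leaving out 1 library. Of the values for single genes, 897 kept direction and side, 189 no longer passed, 21 newly passed and 27 reversed, and for shares of gene lists the counts were 170, 42, 3 and 16. Depth is known only through the background level. Of the 5581 lost regions, 24.2% were called again above the median score, 41.6% with equal numbers and 88.2% at a fold of at least 6. The share called again was 17.9% at a fold of at least 10 and 32.5% where peaks had to cover at least 0.5 of the region. Counts fall to 0 in a step, because too few regions or genes then reach the smallest possible p. Fewer libraries raise the smallest p and stricter lists hold fewer peaks by construction; for the other changes the cause was not tested. Genes under the minimum of peaks in an alternative gave no value there.

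Above the median score, TSS-proximal peaks differed by −0.22 (exact p = 0.186), 1948 regions were lost, 0 genes had fewer and 0 more peaks, and 0 lists passed; ATF3 was at 0.125 and the AP-1 list at −11.2. LNCaP AU-15330 lost 1117 regions. The SMARCA2 guide had a log2 peak number of 0.0204 and 1203 lost regions, the combined group 0.11, a ratio of 0.0541 and 1185 lost regions. The retained share was 13.1% and the odds ratio of loss shared between lines 101.

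With equal numbers, TSS-proximal peaks differed by 0.42 (exact p = 0.00404; by construction the reverse of the distal fall), 2556 regions were lost and 521 gained, 481 genes had fewer and 862 more peaks, and 0 lists passed with a fall, while SWI/SNF and cell cycle (exact adjusted p = 0.0148 each), blood cell (0.0333) and AP-1 genes (24.8 points, 0.0148) passed with a rise. Reversed genes were ACTB 2.38, ATF3 0.125, BRD9 0.5, CD14 0.75, CD4 3.62, CDK1 0.25, E2F1 2.38, ENO2 4.5, FKBP5 0.875, FOXA1 1.12, HOXB13 0.75, KLK3 0.25, LAMB3 2, SMARCA2 0.75 and SPI1 0.75. Reversed lists were androgen response 0.962, lineage factors 2.08, luminal 4.08, basal 4.89, neuroendocrine 5.30, blood cell 25.6, SWI/SNF 14.4, housekeeping 12.8 and cell cycle 25.3 points. LNCaP AU-15330 lost 891 regions, the SMARCA2 guide 574, the SMARCA4 guide 516 (ratio 0.24) and the combined group 611 (ratio 0.0305). The retained share was 26.3%, and the odds ratios of shared loss were 158 between lines and 2.94 between drug and combined group.

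With the 8 h and 24 h libraries alone, peak number differed by −0.84 and TSS-proximal number by −0.22 (exact p = 0.0571 each), 0 regions were lost and 0 gained, 0 genes had fewer and 0 more, 0 lists passed and ACTB was at 0.75. Where peaks had to cover at least 0.5 of a region, 2253 regions were lost and 3 gained, the retained share was 12.0% and the odds ratio of shared loss 32.3. The retained share was 30.8% with the vehicle 8 h pair as reference. With 10 kb on each side 1193 genes had fewer peaks, ACTB was at 0.25, E2F1 at 0.75 and HOXB13 at 1.38; with 100 kb 4533 genes had fewer and GAPDH was at −1.88. With TSS within 5 kb the combined group's ratio was 0.0331. With the replicate block 0 genes had fewer and 0 more.

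At a fold of at least 6, the AP-1 list was at −0.625 and peak number at 0.0444 with the SMARCA2 guide and 0.0234 in the combined group. At a fold of at least 10, TSS-proximal peaks differed by −0.17 (exact p = 0.230), 1608 regions were lost, 0 genes had fewer and 0 more, 4 lists passed, ENO2 was at 1.12, NDRG1 at −2.25 and the AP-1 list at −11.7. LNCaP AU-15330 then lost 805 regions, the SMARCA2 guide 653 (number 0.13), the SMARCA4 guide 1214 (ratio 0.0752) and the combined group 645 (number 0.19, ratio 0.14). With the run folder block 0 genes had fewer and 0 more. Without segments above 100 peaks per Mb 3 regions were gained and 0 genes had more, and above 150 the counts were 4 and 2. Without both vehicle 8 h libraries 0 regions were lost and 0 gained, 0 genes had fewer and 0 more, ACTB was at 0.5 and GAPDH at −0.75. Without both libraries of any 1 drug time 0 genes had fewer and 0 more; 23 regions were gained without 4 h, 20 without 12 h and 18 without 24 h.

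Leaving out each library in turn gave 5631 to 12788 lost and 7 to 25 gained regions, 0 to 4481 genes with fewer and 0 to 11 with more peaks, CD14 at −0.625 to 0.0417, GAPDH at −0.417 to 0.583 and the AP-1 list at −2.44 to 4.95. LNCaP AU-15330 lost 3415 to 8007 and gained 30 to 180 regions. The SMARCA2 guide had a number of −0.0864 to 0.0834, 3171 to 6055 lost and 3277 to 6875 gained regions, the SMARCA4 guide 4851 to 7701 and 1778 to 4337, and the combined group 3743 to 6344 and 3522 to 6282. The retained share was 15.3% to 19.6%, in LNCaP 8.31% to 13.7% and in the combined group 58.7% to 72.7%. The odds ratio of shared loss was 33.7 to 53.0 (52.99) between lines and 3.004 to 5.02 between drug and combined group.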

Other observations

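Of the tests in this part, those of depth, weak peaks, run folder and splits of the libraries were chosen only after the result was seen.

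The 4 VCaP libraries titled AU-15330 0.5 h and 1 h entered no comparison, since their treatment label names vehicle. They list 48239 and 41931 summits (0.5 h) and 37889 and 38543 (1 h), of which 66.8%, 64.0%, 60.8% and 60.7% were distal. Distal regions shared by the VCaP vehicle 24 h libraries held a summit at 57.8% ± 4.55 (0.5 h) and 31.2% ± 1.90 (1 h; SD, n = 2 each), beside 60.1% in vehicle 8 h and 18.4% ± 2.12 under AU-15330 at 4 to 24 h (SD, n = 8). In summit windows the forkhead motif of FOXA factors was in 14.4% of distal peaks in vehicle, 8.81% at 0.5 h and 5.12% at 1 h, the HOXB13 motif in 4.31%, 3.19% and 2.16%, and the CTCF motif in 4.06%, 3.56% and 3.23%.

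The loss of distal regions in VCaP under AU-15330 was set against 4 technical explanations. The AU-15330 library was the deeper one in 16 pairs and had fewer distal peaks in all 16 (a share of 1, as in every pair), against lower depth in AU-15330 libraries. At equal vehicle score, against weak peaks falling below the peak threshold, distal regions were lost more often than TSS-proximal ones (odds ratio 19.9, 95% interval 18.1 to 21.9, 19604 regions), and at equal GC content and score the odds ratio was 4.18 (3.74 to 4.66). Within the run folder with the smaller fall the log2 ratio differed by −1.004, against the folder. None of these 4 is then the whole explanation, and loss of remodelling at distal sites under the compound may be one, a hypothesis from these data that no test here addressed.

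The 9 VCaP genes with more peaks under AU-15330 lay in dense segments, 7 of them in 1 segment of chromosome 13 with a mean of 944 (944.5) peaks in vehicle and 1656 under AU-15330, while the segment of chromosome 8 from 46174256 to 46384798 went from 56 to 17.8 (17.75). The median fold of AU-15330 peaks in the 9 loci was 6.42, at percentile 22.9 of AU-15330 peaks elsewhere, below the bound of 25 set for a raised background in segments with many copies. At a fold of at least 10 the loci held 0.715 times as many peaks under AU-15330 as in vehicle, which argues against new open sites of ordinary strength. In vehicle libraries the peaks of these loci were as weak (median fold 6.25, percentile 17.3), so weak peaks alone do not account for a higher number under AU-15330, and whether a raised background does cannot be told from these values. Chance stays open for their number, copy number was not measured, and no biological explanation was tested.

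Splits of the 12 VCaP libraries into 4 and 8 (100, the real one included) were compared by the number of regions or genes at the smallest possible p, since the adjusted counts fall to 0 in a step. No other of these splits reached the 5581 lost regions (highest other split 154) or the 1879 genes with fewer peaks (highest other 254), so 1 of 100 each. This argues against a chance assignment of these libraries. It does not separate the counts from the shorter AU-15330 lists: with equal numbers of peaks 481 genes had fewer and 862 more. Chance cannot be excluded for the 7 gained regions (14 of 100 splits, highest other 25) or the 9 genes with more peaks (17 of 100, highest other 60). The split with 25 regions set replicate 2 of vehicle 8 h and of AU-15330 4 h, 8 h and 12 h against the rest, and the split with 60 genes the AU-15330 4 h and 12 h libraries, which points to a structure among the libraries. With the replicate block 7 regions were gained and 0 genes had more.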
